A study of Mus musculus with 8 samples.

How the data were processed

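RNA was sequenced from tumour-associated macrophages of 8 C57BL/6 mice, 4 on a control diet (CD, 10% of energy from fat) and 4 on a high-fat diet (HFD, 60% of energy from fat). The diets began 6 weeks before MC38 cells, a mouse colon carcinoma line, were injected into the spleen to seed the liver. Metastases were taken 19 days later, and cells carrying CD45, CD11b and F4/80 were sorted from them. Each library was made from oligo(dT)-primed SMARTer full-length cDNA that was amplified by PCR and then fragmented. The protocol describes no molecular identifiers and no step that marks the strand, so counts are read counts of amplified cDNA.

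The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d. The genome build and the parameters are not given in the sources used here. The deposited table held, for each of the 8 libraries and 42649 genes, FPKM as computed by the authors (fragments per kilobase of transcript, scaled by the fragments of the library) and raw counts per gene, which the authors had not normalised. The 8 count columns held whole numbers with totals that differed between libraries, and the FPKM columns were proportional to count over length and depth. Of the 42649 gene identifiers, 42502 were found in GENCODE release M21 of build GRCm38 and 39410 of those had the same start and end, so positions are given on that build.

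The choice of tests, gene lists, named genes and alternative settings was fixed before the data were examined, with a count-based test to be used if the table held counts. Counts were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test, diet as the only term, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 17367 genes that passed the filter and a threshold of 0.05. These genes held 99.6% to 99.9% of the counts of each library. Levels are given as TMM-scaled CPM from edgeR, mean ± SD with n = 4 per diet, and changes as log2 fold change, HFD minus CD, ± SE. Symbols shared by more than 1 identifier (68) were kept apart by identifier.

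Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes of 0.01), with Benjamini-Hochberg adjustment over the 46 pathway and cell type lists with at least 5 tested members. Each list was also tested with an estimated correlation and with fry, and its members were counted once adjusted over all genes and once adjusted over the list alone. The marker lists measure transcripts of other cell types that the gate could hold in bulk libraries, and no single cell is identified by them. A panel of 26 genes chosen for the question was reported in every case.

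Genes were named by a rule. Of the genes past the threshold with all 4 HFD values on one side of all 4 CD values, the 10 largest changes in each direction were taken, with predicted-only symbols passed over but counted. Where fewer passed, the genes with the smallest p filled up to 5 per direction and are given as values that did not pass. Of each list described, up to 4 passing members were taken, or 3 by smallest p as values.

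Total counts ran from 37180157 to 55717378 per library. At 100 counts the counting error is 10%, and the spread between libraries of one diet was larger. The median chi-square per gene was 4.05 to 34.1 between pairs of such libraries, where sampling noise alone gives 0.455. Where all libraries of a diet had 0 counts, a fold is given as a lower bound against 3 counts over that group. Such floors cover counting error only, since PCR copies are not independent molecules. The tests were tried on simulated data with the same totals and spread. With diet as the only term 1% of seeded 2-fold and 18% of seeded 4-fold changes were recovered, and with a term for replicate numbers 1 and 2 against 3 and 4 it was 2% and 45%.

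Whether replicate numbers pair the CD and HFD samples was checked from the deviation of each library from its group mean, correlated across genes. Same-number libraries correlated at 0.11, 0.29, 0.22 and 0.18, libraries with different numbers within 1 and 2 or within 3 and 4 correlated at 0.16 to 0.32, and libraries from opposite sides correlated negatively. A block for replicate number was therefore run as an alternative. After the data had been examined, a term for replicate numbers 1 and 2 against 3 and 4 was added. Fits within each side, a fit without CD replicates 3 and 4 and a test of the interaction of diet with that division were added too. So were a fit scaled by library size only, DESeq2 on the genes of the edgeR filter, and the division term with HFD replicate 1 left out or with the mean of the neutrophil list as a covariate. The fit without CD replicates 3 and 4 sets CD replicates 1 and 2 against HFD replicates 1 to 4, with no term for the division. Diet is mixed with the division of replicate numbers there, so a change in that fit can reflect either. No label names a batch, and what the replicate numbers stand for is not given in the sources used here.

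The alternative settings fixed at that point were limma on log2(FPKM + 1) with a mean FPKM of at least 1, pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, a TPM scale, quantile normalization, a median shift per library and library weights. Further ones were robust moderation, the replicate block, the mean of the hepatocyte list as a covariate, leaving out each library in turn, RLE factors, DESeq2 1.42.0, an unadjusted p under 0.05 with at least a 2-fold change, camera with an estimated correlation and fry. No library was left out of the main comparison.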

Results

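Gene expression was measured by RNA sequencing in 8 libraries of tumour-associated macrophages sorted from MC38 liver metastases, 4 from CD-fed and 4 from HFD-fed mice. Total counts were 51299686, 52008248, 43857205 and 37180157 in CD replicates 1 to 4. They were 47132061, 55717378, 44997865 and 50233846 in HFD replicates 1 to 4. The sort markers were present in every library. Ptprc, which encodes CD45, averaged 114 ± 42.6 CPM in CD and 78.1 ± 24.2 in HFD (SD, n = 4). Itgam, which encodes CD11b, averaged 91.4 ± 41.3 and 76.2 ± 47.0.

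CD replicates 3 and 4 stood apart from the other 6 libraries. At least 1 count was found for 34495 and 33449 genes in these libraries, against 21571 to 24556 in the others. Some gene families are normally silent outside specialised tissues, such as olfactory, vomeronasal and taste receptors, keratin-associated proteins and beta-defensins. These 1329 genes took 263 and 275 CPM there, 59.7 and 65.8 in CD replicates 1 and 2, and 30.4 to 43.6 in the HFD libraries. They were thus higher in every CD library than in every HFD library. The mean of the neutrophil list was 7.61 and 7.64 log2 CPM in CD replicates 3 and 4 and 3.71 to 4.91 in the others. Ribosomal protein transcripts took 1.65% and 1.87% of the counts there and 5.05% to 6.32% elsewhere. Mitochondrially encoded transcripts took 9.15% and 10.7% of the counts there and 2.58% to 7.68% elsewhere. The 9 genes at the start of chromosome 9 took 384 and 316 CPM there and 2.25 to 31.6 elsewhere. The first principal component held 43.9% of the variance and placed CD replicates 3 and 4 at 130.4 and 134.2, and the other libraries between -88.3 and -8.88.

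**Figure D1:**
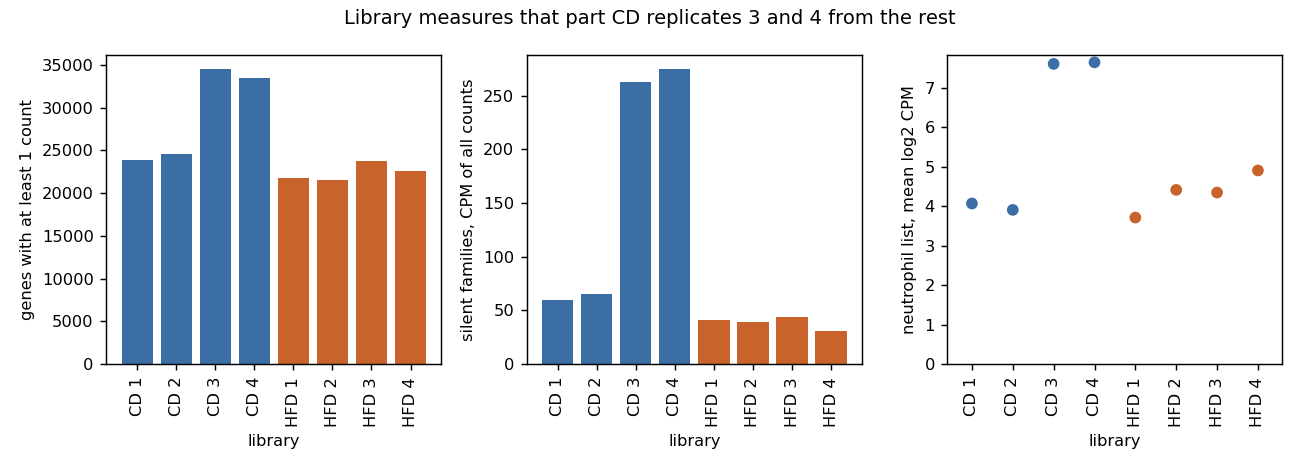
Number of genes with at least 1 count (bars from 0), CPM in normally silent gene families (bars from 0) and mean log2 CPM of the neutrophil list (points) for each of the 8 libraries, with CD in blue and HFD in orange. CD replicates 3 and 4 have 34495 and 33449 genes with a count, and the other libraries 21571 to 24556.

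The main comparison asks how macrophages of metastases in HFD-fed mice differ from those in CD-fed mice. By camera, interferon-stimulated, inflammatory cytokine, hepatocyte, T cell and NK cell transcripts were lower in HFD as groups, and those of fatty acid oxidation, Kupffer cells and the cell cycle were higher. All of these calls were lost with an estimated correlation (adjusted p = 0.125 to 0.527 with an estimated correlation), and that of cell cycle genes also without CD replicates 3 and 4. A single gene passed the threshold over all genes. It was Ass1, which encodes argininosuccinate synthase of the urea cycle and arginine synthesis. It fell from 24.2 ± 1.24 to 5.68 ± 0.541 CPM (SD, n = 4).

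Ass1 (ENSMUSG00000076441, chromosome 2, 31470207 to 31520672, GRCm38) had a log2 fold change of -2.09 ± 0.21 (SE). It was lower in 4 of 4 HFD libraries (adjusted p = 0.0268 in edgeR). The count of genes called higher was 0 in edgeR, with 922 at an unadjusted p under 0.05 on the higher side and 1313 on the lower side. Chance alone gives 868 such genes in both directions together. DESeq2 called 153 genes higher and 1075 lower, with 569 of the latter outside the edgeR filter. On log2(FPKM + 1), limma called 0 in either direction (619 at an unadjusted p under 0.05), and with library weights it called 64 higher and 65 lower. All 4 HFD values lay above all 4 CD values for 620 genes and below them for 834, or 8.37% of the genes tested, where chance gives 2.86%. The Ass1 call was lost with any of the 8 libraries left out (adjusted p 0.0829 to 0.194 in edgeR) and with the replicate block (adjusted p = 0.133 in edgeR). It was also lost with the hepatocyte covariate (adjusted p = 0.153, Ass1 log2 fold change -2.29), with library size only (adjusted p = 0.479) and with limma on log2(FPKM + 1) and on the TPM scale (adjusted p = 0.536 and 0.541). Hepatocytes express Ass1 as well, and the hepatocyte list was lower in the same 4 HFD libraries (median -1.28). Ass1 did not follow Alb, a member of that list. In CD Ass1 ran from 22.5 to 25.4 CPM and Alb from 6.36 to 20.7. In HFD Ass1 ran from 5.02 to 6.15 CPM and Alb from 3.85 to 18.01. Hpx, another member, was even in CD as Ass1 was (14.3 to 17.6 CPM). Whether hepatocyte RNA accounts for the fall of Ass1 is therefore not decided. With libraries left out the Ass1 log2 fold change stayed between -2.14 and -2.03.

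The genes of smallest p beside Ass1 did not pass. The smallest on the higher side was that of Slc27a1, which encodes a fatty acid transport protein. It was at 10.1 ± 0.576 CPM in CD and 32.9 ± 5.21 in HFD (log2 fold change 1.70 ± 0.22, adjusted p = 0.0941 in edgeR). Angptl4, a PPAR target that encodes an inhibitor of lipoprotein lipase, was at 1.98 ± 0.604 and 7.62 ± 1.68 CPM. The apolipoprotein gene Apoc4 was at 2.48 ± 0.0983 and 7.76 ± 1.93. The large scaffold gene Ahnak2 was at 4.14 ± 1.10 and 16.2 ± 3.58 CPM. The cold-inducible RNA-binding protein gene Cirbp was at 7.58 ± 2.09 and 27.9 ± 6.57 CPM. On the lower side stood plasma protein genes that hepatocytes express. Hpx (hemopexin) was at 16.1 ± 1.42 and 4.00 ± 0.914 CPM. Fgb (fibrinogen beta chain) was at 16.5 ± 6.83 and 2.77 ± 0.825, and Vtn (vitronectin) at 3.65 ± 0.578 and 0.812 ± 0.208. Stfa3, a stefin A gene expressed in neutrophils, was at 1.57 ± 0.940 CPM in CD and had 0 counts in all HFD libraries, which makes it at least 108-fold lower. Adjusted p values of these genes other than Slc27a1 ran from 0.0883 for Hpx to 0.150 in edgeR.

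**Figure D2:**
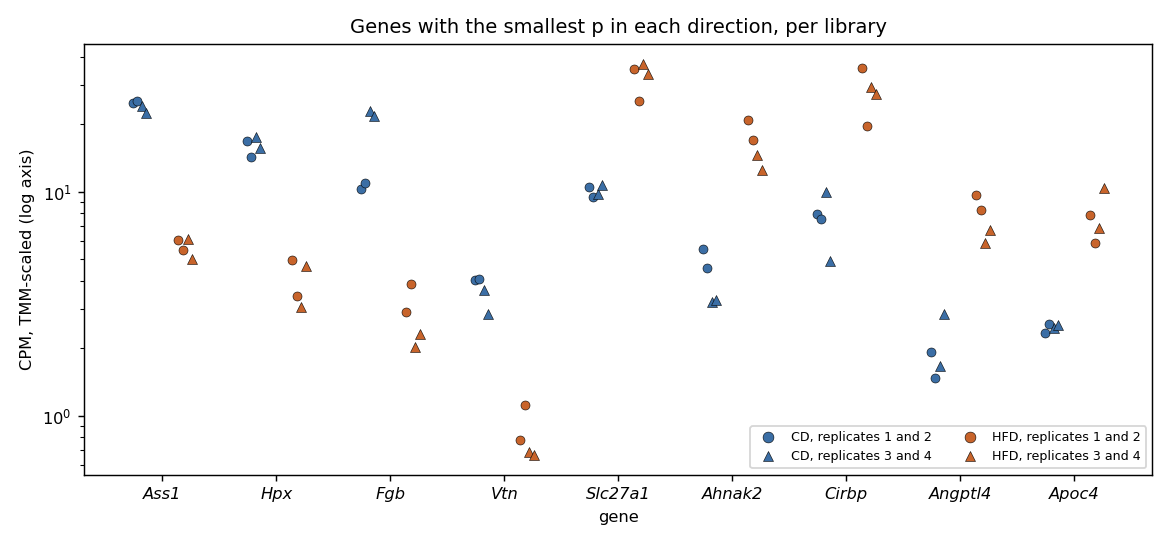
TMM-scaled CPM (log axis) of Ass1 and of 8 of the genes with the smallest p in either direction, 1 point per library, with circles for replicates 1 and 2 and triangles for replicates 3 and 4. The 4 HFD values lie on one side of the 4 CD values for each gene shown, and Ass1 alone passed the adjusted threshold, with 24.2 CPM in CD and 5.68 CPM in HFD on average.

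Of the 46 lists, 23 were called by camera, 6 higher and 17 lower in HFD, and 0 of these calls held with an estimated correlation. The fry test called 4 lists: interferon gamma induced genes, fatty acid oxidation and PPAR targets, hepatocytes, and the joint list of eosinophils, mast cells and basophils. Over the 8 libraries 0 members of these lists had a diet group without counts, so each median rests on fitted values of genes with counts in both diets.

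Type I interferon response genes fell together in HFD in the main test, and the list was called higher in HFD with the mean of the hepatocyte list as a covariate (median 0.49, adjusted p = 0.0124 with camera). The hepatocyte list mean was itself lower in 4 of 4 HFD libraries, so that fit cannot tell the covariate from diet. The mean of the type I list was 6.26 ± 1.06 log2 CPM in CD and 4.82 ± 0.33 in HFD (SD, n = 4), lower in 4 of 4 HFD libraries. None of the 35 tested members had a positive log2 fold change. The median was -1.50 (adjusted p = 1.6e-15 with camera, adjusted p = 0.379 with an estimated correlation). Of the members, 26 were lower and 0 higher adjusted over the list alone. Over all genes 0 passed in edgeR, with 28 members lower at an unadjusted p under 0.05. Zbp1, a sensor of nucleic acids, was at 125 ± 74.2 CPM in CD and 34.7 ± 5.91 in HFD. Usp18, which restrains interferon signalling, was at 151 ± 121 and 26.9 ± 11.1, and Parp14 at 76.7 ± 48.1 and 21.3 ± 5.19. The list mean in CD replicates 3 and 4, which also had the highest neutrophil list means, was 7.16 and 7.21 log2 CPM, against 5.37 and 5.31 in CD replicates 1 and 2. Without CD replicates 3 and 4 the median was -0.39 and the list was still called (adjusted p = 9.0e-07 with camera).

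Genes induced by interferon gamma also fell as a group, and did so with camera in each of 28 alternative fits. Their list mean was 4.94 ± 0.22 log2 CPM in CD and 3.91 ± 0.20 in HFD (SD, n = 4), lower in 4 of 4 HFD libraries. The median was -0.92 (adjusted p = 1.6e-10 with camera, adjusted p = 0.125 with an estimated correlation). Of the 26 tested members, 9 were lower adjusted over the list alone and 0 over all genes (edgeR, 12 lower at an unadjusted p under 0.05). In the alternative fits the median of interferon gamma induced genes ran from -1.17 to -0.31, the latter with limma on the TPM scale. The immunity-related GTPases that act on vacuoles of intracellular pathogens gave the smallest p values. Irgm1 was at 79.7 ± 51.8 and 16.1 ± 4.51 CPM, Igtp at 56.1 ± 25.8 and 17.3 ± 3.95, and Irgm2 at 12.4 ± 9.35 and 2.80 ± 1.15. Inflammatory cytokines and NF-kB targets fell with them, from 6.81 ± 0.96 to 5.42 ± 0.34 log2 CPM (SD, n = 4), lower in 4 of 4 HFD libraries. The median was -1.37 (adjusted p = 1.9e-12 with camera, adjusted p = 0.314 with an estimated correlation). Of 33 members, 18 were lower adjusted over the list alone and 0 over all genes (edgeR, 20 lower at an unadjusted p under 0.05). Acod1, which makes itaconate, was at 840 ± 812 CPM in CD and 54.5 ± 23.3 in HFD. Tnf was at 220 ± 135 and 54.2 ± 20.6, and the TNF receptor adaptor Traf1 at 71.8 ± 17.5 and 28.0 ± 11.9. Without CD replicates 3 and 4 the median of the NF-kB list was -0.35 (adjusted p = 3.6e-05 with camera). It was -0.42 within replicate numbers 1 and 2 and -2.16 within 3 and 4 (interaction adjusted p = 8.1e-14 with camera, adjusted p = 0.218 with an estimated correlation). Acod1 is also a member of the neutrophil list.

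**Figure D3:**
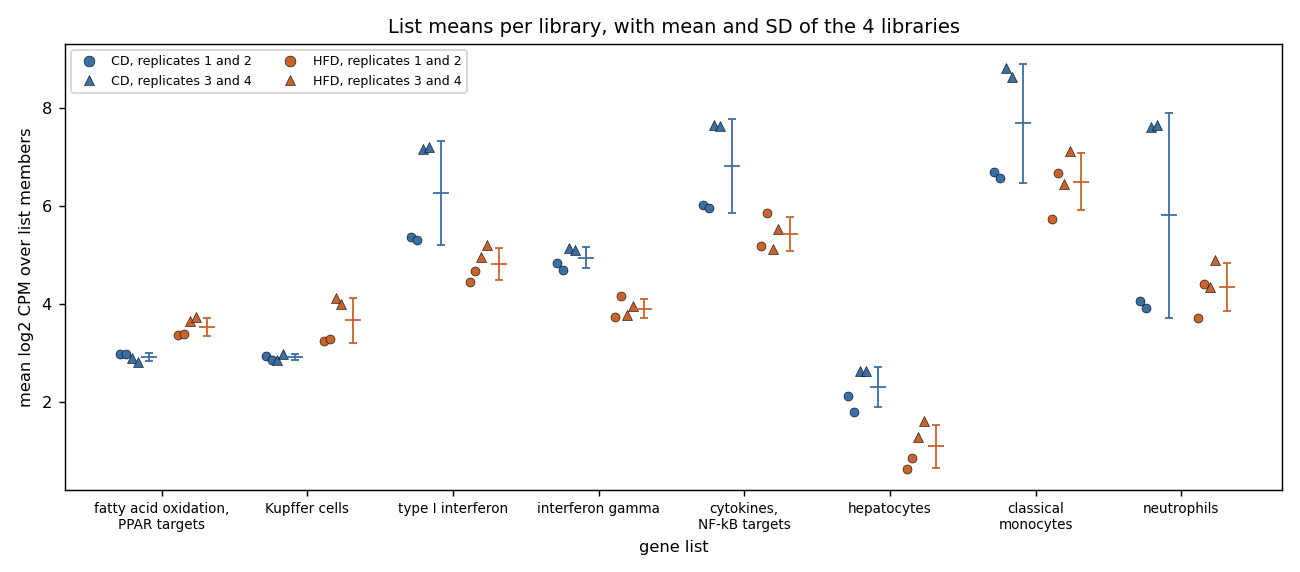
Mean log2 CPM over the members of 8 lists, 1 point per library, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and a bar for the mean and SD of the 4 libraries of each diet. HFD lies below CD in all libraries for type I interferon (4.82 against 6.26 on average) and above CD in all libraries for fatty acid oxidation (3.53 against 2.91), while the neutrophil and classical monocyte lists overlap between diets.

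Fatty acid oxidation and PPAR target genes rose as a group in HFD, in the main test and with camera in each of 28 alternative fits. The list mean was 2.91 ± 0.08 log2 CPM in CD and 3.53 ± 0.18 in HFD (SD, n = 4), higher in 4 of 4 HFD libraries. The log2 fold change was above 0 in 21 of 27 members, with a median of 0.65 (adjusted p = 3.4e-05 with camera, adjusted p = 0.131 with an estimated correlation). Adjusted over the list alone 3 members were higher and 0 lower, with 0 over all genes (edgeR, 11 higher at an unadjusted p under 0.05). These were Angptl4, the mitochondrial acyl-CoA thioesterase gene Acot2 and Acaa2. Acot2 was at 1.78 ± 0.417 CPM in CD and 27.1 ± 41.2 in HFD, with 88.9 CPM in HFD replicate 1 and 3.30 to 8.37 in the other 3. The Acot2 log2 fold change was 3.92, and 1.86 without HFD replicate 1. Acaa2 encodes the last enzyme of the mitochondrial beta-oxidation spiral and was at 23.5 ± 3.54 and 45.4 ± 7.22 CPM. The median of the list was 0.37 without CD replicates 3 and 4, within replicate numbers 1 and 2 it was 0.38, and the lowest was 0.14 in fatty acid oxidation and PPAR targets with the hepatocyte covariate. Kupffer cell markers rose as a group as well, from 2.91 ± 0.06 to 3.66 ± 0.46 log2 CPM (SD, n = 4), in 4 of 4 HFD libraries. The median was 0.77 (adjusted p = 1.1e-04 with camera, adjusted p = 0.314 with an estimated correlation). Of their 15 members, 4 were higher adjusted over the list alone and 0 over all genes (edgeR, 7 higher at an unadjusted p under 0.05). The scavenger receptor Marco was at 33.6 ± 9.42 and 110 ± 29.9 CPM, the lectin Clec4f at 48.0 ± 13.9 and 112 ± 44.6, and the complement gene C6 at 2.81 ± 1.22 and 7.76 ± 3.06. Other lists also hold 7 of the 15 markers. The Kupffer cells list was not called within replicate numbers 1 and 2 (median 0.23, adjusted p = 0.0527 with camera).

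Markers of several other cell types were lower in HFD. Hepatocyte transcripts fell from 2.29 ± 0.41 to 1.09 ± 0.44 log2 CPM (SD, n = 4), in 4 of 4 HFD libraries. The median was -1.28 (adjusted p = 4.3e-10 with camera, adjusted p = 0.304 with an estimated correlation). Of 26 hepatocyte members, 12 were lower and 2 higher adjusted over the list alone, and 0 over all genes (edgeR, 14 lower and 2 higher at an unadjusted p under 0.05). The higher ones, Trf (transferrin) and Apoc1 (an apolipoprotein that macrophages also express), are named because their values stood out. Hpx and Fgb above and Fgg (fibrinogen gamma chain, 7.57 ± 3.73 CPM in CD and 1.39 ± 0.271 in HFD) had the smallest p values of this list. The hepatocytes list had a median of -0.72 without CD replicates 3 and 4 (adjusted p = 3.5e-07 with camera), and with a mean FPKM of at least 5 it was not called (median -0.35, adjusted p = 0.430 with camera). The T cell list fell from 0.35 ± 0.39 to -0.93 ± 0.54 log2 CPM (SD, n = 4), in 4 of 4 HFD libraries. Its median was -1.14 (adjusted p = 4.3e-06 with camera, adjusted p = 0.304 with an estimated correlation). The NK cell list fell from 0.85 ± 0.30 to -0.24 ± 0.48 (SD, n = 4), in 4 of 4 HFD libraries. Its median was -1.15 (adjusted p = 0.00511 with camera, adjusted p = 0.314 with an estimated correlation). These transcripts were scarce, and counts in normally silent families were likewise lower in every HFD library than in every CD library. The T cell receptor complex gene Cd3g was at 2.65 ± 0.328 CPM in CD and 0.944 ± 0.668 in HFD. The cytotoxic granule gene Gzmb was at 1.78 ± 0.298 and 0.737 ± 0.247. In both lists 0 members passed adjusted over the list alone (edgeR, 4 T cell and 2 NK cell members lower at an unadjusted p under 0.05). The medians were -0.45 for T cells and -0.65 for NK cells without CD replicates 3 and 4, and both were called. Within replicate numbers 1 and 2 neither the T cells list (median -0.35, adjusted p = 0.0706 with camera) nor the NK cells list (median -0.46, adjusted p = 0.558 with camera) was called, and the NK cells list was also not called with no filter on low counts (adjusted p = 0.312 with camera) or with the division of replicate numbers and the neutrophil covariate (adjusted p = 0.566 with camera).

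Classical monocyte and neutrophil lists were called lower in HFD with all 8 libraries and not without CD replicates 3 and 4. The classical monocyte list had a median of -1.55 (adjusted p = 7.5e-04 with camera, adjusted p = 0.597 with an estimated correlation), with 4 of 13 members lower adjusted over the list alone. Plac8 was at 2427 ± 1605 CPM in CD and 317 ± 281 in HFD. Ly6c2, the Ly6C antigen gene, was at 846 ± 755 and 121 ± 91.4, and Gm9733 at 11.9 ± 5.84 and 4.04 ± 1.97. The neutrophil list had a median of -2.91 (adjusted p = 0.0141 with camera, adjusted p = 0.68 with an estimated correlation), with 11 of 18 members lower and 1 higher, adjusted over the list alone. The higher one, Camp, is named because its value stood out. The lipolysis inhibitor G0s2 was at 696 ± 750 CPM in CD and 31.0 ± 18.2 in HFD and Stfa2l1 at 37.0 ± 41.8 and 1.47 ± 1.24. Without CD replicates 3 and 4 the classical monocyte median was -0.18 (adjusted p = 0.929 with camera). The neutrophil list was then called higher in HFD, with a median of 0.62 (adjusted p = 0.0108 with camera). Within replicate numbers 1 and 2 the neutrophil list was not called (median 0.32). Leaving out CD replicate 3 or 4 alone already ended the call of the list of neutrophils (adjusted p = 0.101 and 0.121 with camera).

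Cell cycle genes rose as a group, from 2.71 ± 0.92 to 3.62 ± 0.05 log2 CPM (SD, n = 4), with HFD above CD in 4 of 4 libraries. The log2 fold change was above 0 in 38 of 39 members, with a median of 0.75 (adjusted p = 3.9e-11 with camera, adjusted p = 0.527 with an estimated correlation). Adjusted over the list alone 0 members passed in edgeR, with 7 higher at an unadjusted p under 0.05. The mitotic genes Prc1 (4.24 ± 1.05 and 8.66 ± 2.83 CPM) and Cenpa (14.4 ± 6.46 and 31.3 ± 7.11) had the smallest p values. Ribosomal protein genes had a median of 0.49 (adjusted p = 4.3e-06 with camera, adjusted p = 0.68 with an estimated correlation), all 51 above 0, with Rps2 at 313 ± 112 and 671 ± 89.8 CPM. Without CD replicates 3 and 4 neither list was called: the medians were 0.11 for cell cycle genes (adjusted p = 0.225 with camera) and 0.10 for ribosomal proteins (adjusted p = 0.665 with camera). Within replicate numbers 1 and 2 the ribosomal proteins list was called lower in HFD (median -0.32, adjusted p = 0.0410 with camera).

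None of the 26 panel genes passed over all genes tested (edgeR, 6 higher and 5 lower at an unadjusted p under 0.05), and 4 higher and 4 lower passed adjusted over the list alone. The higher ones were Adgre1, which encodes F4/80 (158 ± 71.8 CPM in CD, 466 ± 224 in HFD), the mannose receptor Mrc1, the fatty acid receptor Cd36 and Clec4f. Mrc1 was at 13.3 ± 8.41 and 50.6 ± 31.1 CPM, and Cd36 at 11.7 ± 1.9 and 21.4 ± 6.89. The Mrc1 log2 fold change was 0.45 in replicate numbers 1 and 2 and 3.59 in 3 and 4 (interaction adjusted p = 0.00996 in edgeR). The lower ones were Il1b (11544 ± 10315 and 1246 ± 772), Tnf, Ly6c2 and the T cell chemoattractant Cxcl9 (29.1 ± 20.9 and 10.4 ± 1.67). Among genes that did not pass, the log2 fold change was -0.50 ± 0.66 for Arg1, -2.74 ± 1.3 for Nos2 and -1.03 ± 0.38 for Cd274 (PD-L1). It was 0.95 ± 0.59 for Trem2, -0.95 ± 0.85 for Spp1 and 1.60 ± 0.89 for Apoe. The complement gene C1qa was at 2.17 ± 0.93, the lipid droplet gene Plin2 at 0.58 ± 0.62, Pparg at -0.45 ± 0.33, Cpt1a at 0.75 ± 0.34 and Abca1 at -0.04 ± 0.42. The remaining panel genes were Csf1r at 0.70 ± 0.40, Ptprc at -0.55 ± 0.36 and Itgam at -0.26 ± 0.47. Vegfa was at 0.13 ± 0.37, H2-Ab1 at -1.06 ± 0.90, Ccr2 at -0.59 ± 0.38 and Timd4 at 0.35 ± 0.37. For some of these genes the direction differed between replicate numbers 1 and 2 and numbers 3 and 4. Trem2 was at -0.46 and 2.79 (interaction adjusted p = 0.00864 in edgeR) and C1qa at -0.42 and 4.85 (0.00996). Csf1r was at -0.31 and 1.497 (0.04002), H2-Ab1 at -1.697 and 1.63 (0.0388) and Apoe at -0.56 and 3.11 (0.112). Of the genes that passed over the list alone, Clec4f was at 0.33 and 2.02 (0.0388) and Cxcl9 at -2.12 and -0.15 (0.0243). Leaving out CD replicates 3 and 4 turned the direction for Nos2 (1.51), Arg1 (0.84), Abca1 (0.43), Itgam (0.40) and Spp1 (0.12), and the log2 fold change was -1.09 for Il1b, -0.94 for Tnf and -0.70 for Ly6c2. That fit sets CD replicates 1 and 2 against HFD libraries of all replicate numbers. Within replicate numbers 1 and 2 and within 3 and 4, Nos2 stayed lower (-0.91 and -2.84). So did Arg1 (-0.33 and -0.55), Itgam (-0.43 and -0.20) and Spp1 (-1.56 and -0.82), with Abca1 at -0.18 and 0.02.

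With the mean of the hepatocyte list as a covariate the lists of classical monocytes (median 0.98) and neutrophils (median 2.28) were also called higher in HFD by camera, and the cell cycle and NF-kB lists were not called. The covariate itself separates the diets, so this fit cannot tell it from diet. Blocking on replicate number kept the calls of all lists named above and added 3: hypoxia response, alternative activation and immunosuppression, and fibroblasts and stellate cells (adjusted p = 0.0494, 0.0494 and 0.0453 with camera).

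Replicate numbers 1 and 2 parted from 3 and 4 in both diets, and the diets were compared again with that division as a term in edgeR, a comparison chosen after the data were seen. Phgdh of serine synthesis, the matrix gene Thbs2 and the tetraspanin gene Cd81 were among the largest rises in HFD, and the serum amyloid gene Saa2 and the stefin gene Stfa3 among the largest falls. In all, 179 genes rose and 177 fell over all genes tested. Of these 356, 190 had non-overlapping groups. With the replicate block in its place 0 of these genes were called in edgeR (1270 higher and 1357 lower at an unadjusted p under 0.05).

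Of the genes that rose with non-overlapping groups (74, of which 8 with predicted-only symbols were passed over), 10 had the largest log2 fold changes. Hrct1 was at 3.25 ± 0.40, Shisal2b at 2.98 ± 0.57 and the sulfotransferase Sult1a1 at 2.69 ± 0.37 (SE). The tetraspanin Cd81 was at 2.56 ± 0.51, the cytochrome c oxidase subunit Cox6a2 at 2.34 ± 0.42 and Tgfb3 at 2.17 ± 0.44. Phgdh, the first enzyme of serine synthesis, was at 2.13 ± 0.43 and Enho at 2.10 ± 0.33. The matricellular thrombospondin Thbs2 was at 2.04 ± 0.31 and the lysosomal protease Ctsf at 2.00 ± 0.35. Their adjusted p values ran from 0.0236 for Hrct1 to 0.0419 in edgeR. The change was larger in replicate numbers 3 and 4 than in 1 and 2 for Shisal2b (4.41 and 1.59, interaction adjusted p = 0.00729), Tgfb3 (3.29 and 1.09, 0.0119), Phgdh (3.20 and 1.06, 0.0112), Thbs2 (2.81 and 1.3, 0.0295) and Sult1a1 (3.56 and 1.81, 0.0362). In the fit without CD replicates 3 and 4 and without the term, 0 genes were called in edgeR (502 higher and 428 lower at an unadjusted p under 0.05). The log2 fold change was then 1.07 for Cd81, 1.51 for Cox6a2, 1.15 for Tgfb3 and 1.23 for both Phgdh and Thbs2. Phgdh was at 20.5 ± 13.5 CPM in CD and 75.1 ± 11.3 in HFD, Thbs2 at 6.06 ± 3.64 and 21.6 ± 1.45, and Cd81 at 102 ± 95.3 and 387 ± 269 (SD, n = 4). Of the genes that fell with non-overlapping groups (116, of which 22 were passed over), Saa2, an acute-phase serum amyloid A gene, had a log2 fold change of -7.20 ± 0.70. It was at 4.95 ± 4.31 CPM in CD and 0.0356 ± 0.0712 in HFD. Adora1 was at -5.90 ± 0.97 and Scn3a at -5.49 ± 1.12. Without CD replicates 3 and 4 and without the term, Saa2 was at -5.22, Adora1 at -4.03 and Scn3a at -4.12. The others given here had 0 counts in all HFD libraries. Beside Stfa3, Igsf9b was at least 69.6-fold lower and Ces3a at least 42.3-fold lower. The epidermal genes Rptn, Krt2 and Flg were at least 52.2-fold, 49.8-fold and 47.5-fold lower. These were scarce transcripts, and 40 of the 177 genes that fell had a mean under 1 CPM. Counts in normally silent families were also lower in every HFD library than in every CD library. Whether background reads account for these falls was not tested.

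With the same term Slc27a1, Ahnak2, Cirbp, Angptl4 and Apoc4 rose and Ass1, Hpx, Fgb and Vtn fell (adjusted p 0.00912 for Ass1 to 0.0271 for Angptl4 in edgeR). Among genes named from the lists, the efferocytosis receptor Mertk rose by 1.76 ± 0.29, Marco by 1.72 ± 0.30 and the stress-induced pseudokinase Trib3 by 1.11 ± 0.20 on the log2 scale. Interferon-induced genes fell, with Irgm1 at -2.05 ± 0.33, Irgm2 at -1.86 ± 0.29 and Usp18 at -2.10 ± 0.40. Zbp1 was at -1.62 ± 0.34 and the high-affinity IgG receptor Fcgr1 at -1.17 ± 0.23. Among the others that fell, the monocyte genes Ly6c2 and Plac8 were at -2.31 ± 0.49 and -2.81 ± 0.51. The PD-1 ligand Pdcd1lg2 was at -2.42 ± 0.43, Cd24a at -2.41 ± 0.41 and the chemokine Ccl22 at -1.52 ± 0.29. The EGFR ligand Areg was at -2.05 ± 0.44, the hexokinase Hk3 at -1.21 ± 0.26 and Timp3 at -1.59 ± 0.31. Sema4d was at -1.08 ± 0.20, Ccr9 at -1.67 ± 0.33 and Fgg at -2.28 ± 0.34 (SE). With CD replicates 3 and 4 left out, and without the term, the log2 fold change was -1.12 for Irgm1, -0.68 for Irgm2, -0.90 for Usp18, -0.81 for Zbp1 and -0.12 for Fcgr1. It was -0.70 for Ly6c2, -1.72 for Plac8, -1.06 for Pdcd1lg2, -1.19 for Cd24a, -1.3 for Areg, -0.59 for Sema4d and -1.03 for Ccr9. The fall was larger in replicate numbers 3 and 4 for Cd24a (-3.42 and -1.41 in 1 and 2, interaction adjusted p = 0.0188), Areg (-3.11 and -1.02, 0.0388) and Fgb (-3.38 and -1.64, 0.0319). Counts by list went both ways against the fit without the term. Adjusted over the list alone, 30 of 35 type I interferon genes and 17 of 26 interferon gamma induced genes were lower. In the same way 17 of 26 hepatocyte genes were lower and 1 higher, and 11 of 27 fatty acid oxidation genes were higher. Lower members were fewer than without the term for inflammatory cytokines and NF-kB targets (16 against 18), neutrophils (6 against 11) and MC38 or other epithelial cells (2 against 4).

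The size of the diet difference was not the same in the 2 pairs of replicate numbers. Within replicate numbers 3 and 4, 1894 genes were higher and 1757 lower in HFD, and within 1 and 2 no gene passed in edgeR (0, with 1170 higher and 930 lower at an unadjusted p under 0.05). Spread differed too: the median chi-square per gene was 21.5 between HFD replicates 1 and 2 and 7.63 between HFD replicates 3 and 4. It was 4.79 and 4.05 for the CD pairs. The difference in counts can therefore also come from spread. The interaction of diet with the division was tested directly in edgeR, and 385 genes passed with a more positive change in numbers 3 and 4 and 284 with a more negative one. Across the 17367 genes the log2 fold changes of the 2 pairs correlated at Pearson r = 0.204 and Spearman rho = 0.182, and 55.96% had the same sign. These are correlations across genes, which are not independent replicates.

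Of the 46 lists, 20 showed such an interaction with camera, and 1 of them, cell cycle genes, also with an estimated correlation. The neutrophil list had medians of 0.32 in numbers 1 and 2 and -3.61 in numbers 3 and 4 (interaction adjusted p = 3.2e-14 with camera, adjusted p = 0.218 with an estimated correlation). Cell cycle genes had medians of 0.11 and 1.58 (interaction adjusted p = 4.0e-18 with camera, adjusted p = 0.0201 with an estimated correlation). Type I interferon genes had medians of -0.69 and -1.83 (interaction adjusted p = 6.8e-11 with camera, adjusted p = 0.169 with an estimated correlation). MHC class II genes, which present antigen to CD4 T cells, went in opposite directions, with medians of -1.48 and 1.31 (interaction adjusted p = 7.4e-08 with camera, adjusted p = 0.228 with an estimated correlation). Kupffer cell markers had medians of 0.23 and 1.33 (interaction adjusted p = 0.00298 with camera, adjusted p = 0.246 with an estimated correlation). T cell markers had medians of -0.35 and -2.04 (interaction adjusted p = 0.00124 with camera, adjusted p = 0.169 with an estimated correlation), and NK cell markers -0.46 and -1.79 (interaction adjusted p = 0.0407 with camera, adjusted p = 0.278 with an estimated correlation). Hepatocyte genes had medians of -1.32 and -1.28, and interferon gamma induced genes -0.73 and -1.13 (interaction adjusted p = 0.0570 with camera). In numbers 1 and 2, 2 hepatocyte genes, and in 3 and 4, 1 NK cell gene, had no count in a diet, and the medians with these at their bound were -1.32 and -1.79. Each pair holds 2 libraries per diet, and CD replicates 3 and 4, with the highest neutrophil list means, are the CD side of the second pair.

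**Figure D4:**
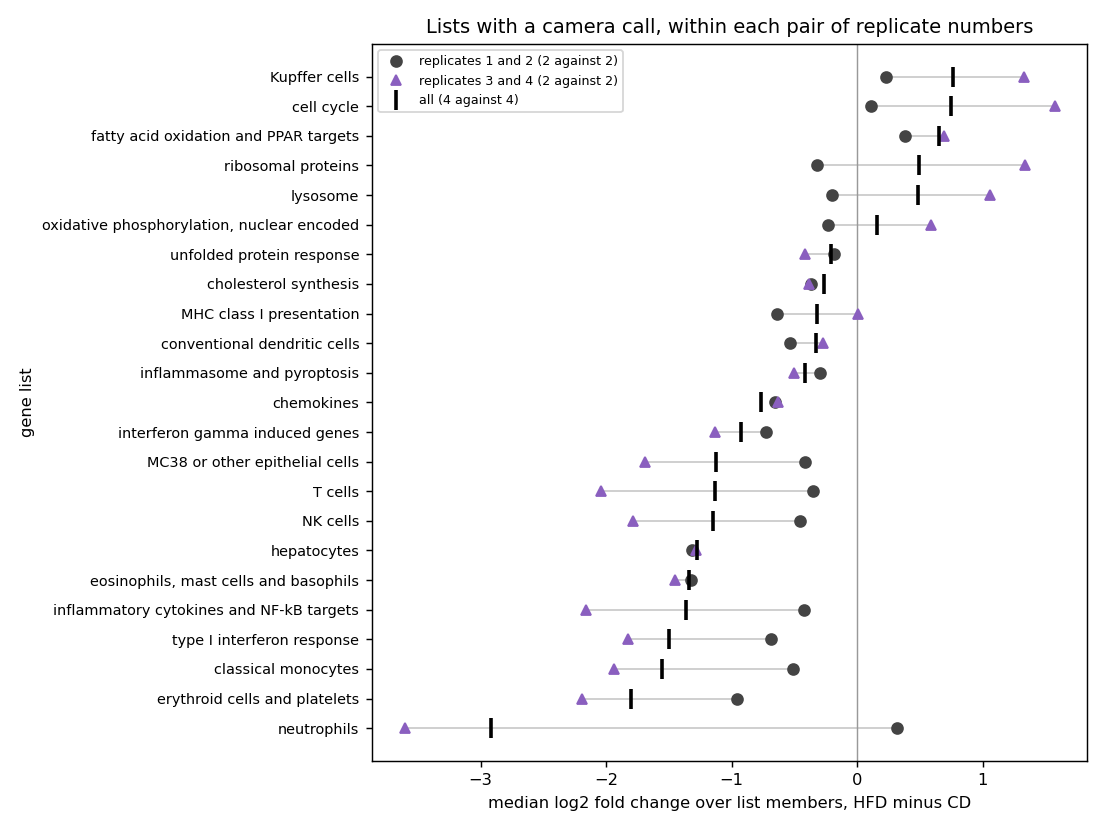
Median log2 fold change (HFD minus CD) over the members of the 23 lists called by camera, within replicate numbers 1 and 2 (circles), within 3 and 4 (triangles) and over all 8 libraries (bars). Hepatocyte genes had similar medians in both pairs (-1.32 and -1.28), and neutrophil genes had medians of 0.32 and -3.61.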

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

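The tests of macrophage share and sequencing depth, of neutrophil content behind the interferon difference, and of unequal falls among hepatocyte transcripts were chosen only after the result was seen, as was the term for replicate numbers 1 and 2 against 3 and 4 used in several of them.

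In 16 of 458 groups of 4 libraries, 1 library lay far from the other 3, where chance gives about 1 in 20 groups, or 22.9. HFD replicate 1 was low for Cd274 (14.0 CPM, others 34.9 to 38.6), Cxcl3 (10.4, others 49.9 to 55.0), Dnajb9 (12.3, others 22.3 to 24.3) and Mt2 (88.4, others 617 to 698). It was high for Sod1 (1236 CPM, others 204 to 262). HFD replicate 3 was low for H2-Ab1 (790 CPM, others 1842 to 2112) and Dgat2 (4.41, others 9.12 to 9.91). It was the one HFD library with counts of Adora1 (0.0949 CPM), Saa2 (0.142 CPM) and Scn3a (0.0712 CPM). HFD replicate 4 was high for Ndufa5 (251 CPM, others 161 to 163) and Reln (0.443, others 0.0738 to 0.119). CD replicate 4 was high for Cd3e (1.82 CPM, others 0.739 to 0.770) and low for Dock1 (1.67, others 2.66 to 2.84). CD replicate 3 was low for Hspa4l (7.04 CPM, others 11.2 to 11.9), and CD replicate 1 was high for the mean of the MHC class I presentation list (7.19 log2 CPM, others 7.04 to 7.06).

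Hepatocyte transcripts were lower in HFD by a median of -1.32 in replicate numbers 1 and 2, -1.28 in 3 and 4 and -0.72 without CD replicates 3 and 4, over 26 genes of which 0 are in another list, although a sort for CD45, CD11b and F4/80 would remove hepatocytes. Composition scaling is excluded as the cause, since the median was -0.94 or lower with TMM, RLE and library size only. Less hepatocyte RNA carried into the HFD libraries would lower abundant hepatocyte transcripts, and 8 of these had a median of -0.69. Among them Alb was at -0.41 ± 0.21 (6.36 to 20.7 CPM in CD, 3.85 to 18.01 in HFD). All 8 are members of the list already seen to fall, so they add no separate support. Unequal falls argue against less carried RNA as the whole cause, since 14 of 25 members lay below Alb by more than 2 combined SE and 2 lay above it. That comparison rests on Alb as the only reference and treats genes of the same libraries as independent, so it does not exclude that cause. A change of hepatocyte expression with diet, seen through the same carried RNA, may account for the rest and was not tested. The proportions of these transcripts also differed among mice of the same diet. In CD replicates 1 and 2 Alb was at 6.75 and 6.36 CPM, below Apoa1 (15.5 and 12.6) and Apoa2 (12.2 and 14.8). In CD replicates 3 and 4 Alb was at 20.7 and 20.05 CPM, above Apoa1 (19.8 and 16.7) and Apoa2 (9.96 and 8.04). Whether hepatocytes were the source of these transcripts was not tested.

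CD replicates 3 and 4 had more genes with a count and more neutrophil transcripts than the other 6 libraries, a higher mitochondrial share (9.15% and 10.7% against 2.58% to 7.68%) and more counts in 9 genes at the start of chromosome 9 (384 and 316 CPM against 2.25 to 31.6), and the labels name no difference between them and the other CD mice, so no biological explanation was tested beyond the mix of sorted cells. A lower share of macrophages that raises every other cell type alike is excluded, since the neutrophil and fibroblast list means moved apart by 5.50 on the log2 scale (3.64 and -1.87). Greater sequencing depth is excluded, since their higher total was 43.9 and the lowest of the others 45.0 (in units of 1e+06 counts). More neutrophils among the sorted cells would raise neutrophil-restricted transcripts, and 8 of these had a median log2 difference of 3.72. Retnlg was at 11989 and 11228 CPM against 50.7 to 442 elsewhere. All 8 belong to the neutrophil list whose high mean was already seen, so they add no separate support. Of the 8, Ly6g, Retnlg, Ngp, Cxcr2, Csf3r and Mmp8 were raised, by 2.42 (Csf3r) to 7.78 (Retnlg). Camp (-1.48) and Ltf (0.24) were not raised, and a sort for F4/80 should remove neutrophils. Background reads spread over genes, such as from genomic DNA, may also be present: across 1329 normally silent genes the counts followed exonic length with Spearman rho = 0.393 in these libraries and 0.210 in the other 6, where genes are not independent replicates.

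Interferon transcripts were lower in HFD in both pairs of replicate numbers. The type I list median of -0.69 in replicate numbers 1 and 2 argues against neutrophil content of CD replicates 3 and 4 as the whole cause. Its bootstrap SE of 0.116 was taken over genes, not mice, and the pair holds 2 libraries per diet, so that cause is not excluded. Composition scaling is excluded by medians of -1.04 or lower with TMM, RLE and library size only. By a covariate, fewer T and NK cells bringing the interferon transcripts cannot be told apart from diet. With the division of replicate numbers as a term the type I median was -1.31, and with the mean of both lists added it was -0.37. Within the pairs of replicate numbers diet explains much of that covariate (R squared 0.724). The list levels do not decide that question. In CD the T and NK list means were 0.35 ± 0.39 and 0.85 ± 0.30 log2 CPM (SD, n = 4). The type I list mean fell from 6.26 ± 1.06 in CD to 4.82 ± 0.33 in HFD. These lists hold different genes, so the gap between their means does not show which cells carried the interferon transcripts. Levels per cell were not measured, so that cause is not excluded. For the larger difference in replicate numbers 3 and 4, neutrophil content cannot be told apart from diet. The median was -0.79 with the division and the neutrophil list mean as a covariate, against -1.31 with the division alone (R squared 0.454). With the hepatocyte list mean as a covariate the type I list was called higher in HFD (median 0.49, adjusted p = 0.0124 with camera). That covariate itself separates the diets (1.80 to 2.63 log2 CPM in CD, 0.62 to 1.60 in HFD), so this fit cannot tell it from diet. The main call was lost with an estimated correlation (adjusted p = 0.379 with an estimated correlation), so the difference is not settled. No test of interferon signalling in the macrophages themselves was made.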

How the results depend on the processing

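The fits with the division of replicate numbers, without CD replicates 3 and 4, within replicate numbers 1 and 2 or 3 and 4, with library size only and with DESeq2 on the genes of the edgeR filter were chosen after seeing the data. Against 0 genes higher and 1 lower in edgeR, the counts were 119 and 296 with no filter on low counts, 64 and 65 with limma library weights, 153 and 1075 with DESeq2, 143 and 496 with DESeq2 on the genes of the edgeR filter, and 510 and 1088 at an unadjusted p under 0.05 with at least a 2-fold change. They were 179 and 177 with the division of replicate numbers, 241 and 295 with that term and HFD replicate 1 left out, and 1894 and 1757 in replicate numbers 3 and 4 only. With 0 higher, the count lower was 2 with quantile normalization and with a median shift per library. It was 0 with limma on log2(FPKM + 1), with a pseudocount of 0.1, on the TPM scale, with the replicate block, with the hepatocyte covariate, with library size only, without CD replicates 3 and 4, in replicate numbers 1 and 2 only, and with the division plus the neutrophil covariate. It was 1 with a mean FPKM of at least 5, robust moderation and RLE factors, and with a pseudocount of 0.5, where the gene was not Ass1. Leaving out each library in turn gave 0 to 0 genes in either direction. The cause of these changes was not tested, except that 569 of the DESeq2 calls lower lie outside the edgeR filter. Of the lists, 23 in the main test, 14 were called with a mean FPKM of at least 5, 14 in replicate numbers 1 and 2 only, 4 with fry and 0 with an estimated correlation, and 17 to 26 in the other settings. The replicate block changed no call other than those given with the results.

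Of 4867 values of the 175 named genes under the alternatives, 4338 stayed on their side of the threshold, 18 no longer passed and 508 passed only there. Of the 4338, 146 in 63 genes changed sign, where neither value passed. The direction turned in 3, all in replicate numbers 3 and 4 only: H2-Ab1 log2 fold change 1.63, H2-Aa log2 fold change 1.19 and Hsph1 log2 fold change 1.22, and the cause was not tested. Scaling moved the median log2 fold change of all genes from 0.01 to 0.36 with limma on log2(FPKM + 1), 0.47 and 0.41 with pseudocounts of 0.1 and 0.5, 0.55 on the TPM scale and 0.42 with library size only. It was -1.01 with no filter and -1.21 with DESeq2, where genes with few counts are included. At this spread between libraries edgeR recovered 18% of simulated 4-fold changes, so a gene that did not pass may still have changed.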

Other observations

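The fit without CD replicates 3 and 4 and the term for the division of replicate numbers were tests chosen only after the result was seen.

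Several other gene groups were lower in HFD with camera on all 8 libraries. Chemokines had a median of -0.76 (adjusted p = 0.0141, adjusted p = 0.379 with an estimated correlation) and were lower in 4 of 4 HFD libraries, with 4 of 24 members lower and 1 higher adjusted over the list alone. Ccl22, a ligand of CCR4, was at 11.1 ± 3.82 CPM in CD and 3.98 ± 2.54 in HFD (SD, n = 4), and the neutrophil chemoattractant Cxcl3 at 377 ± 379 and 42.4 ± 21.4. The joint list of eosinophils, mast cells and basophils had a median of -1.34 (adjusted p = 0.0141, adjusted p = 0.304 with an estimated correlation), with 1 of 6 members, the eotaxin receptor Ccr3, lower adjusted over the list alone. Conventional dendritic cells had a median of -0.33 (adjusted p = 0.0140, adjusted p = 0.314 with an estimated correlation), with 4 of 15 members lower, among them Xcr1 at 5.83 ± 3.02 and 1.61 ± 0.787 CPM. MC38 or other epithelial cells had a median of -1.13 (adjusted p = 0.0112, adjusted p = 0.523 with an estimated correlation), with 4 of 13 lower and 1 higher, and Areg at 19.7 ± 10.7 and 4.27 ± 1.41 CPM. Erythroid cells and platelets had a median of -1.80 (adjusted p = 0.0177, adjusted p = 0.654 with an estimated correlation), with 0 of 13 passing adjusted over the list alone (edgeR, 2 lower and 1 higher at an unadjusted p under 0.05). Without CD replicates 3 and 4 the medians of the epithelial and the erythroid lists were -0.49 and 0.24 and neither was called. Chemokines (median -0.47), the joint list of eosinophils, mast cells and basophils (-0.68) and conventional dendritic cells (-0.84) were still called.

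MHC class I presentation had a median of -0.32 (adjusted p = 0.0181, adjusted p = 0.68 with an estimated correlation), with 2 of 21 members lower adjusted over the list alone, the transactivator Nlrc5 at 19.2 ± 9.35 and 6.68 ± 1.46 CPM and the peptide transporter Tap1 at 25.8 ± 1.79 and 14.9 ± 2.04 (SD, n = 4). Inflammasome and pyroptosis genes had a median of -0.42 (adjusted p = 0.0181, adjusted p = 0.68 with an estimated correlation), with Il1a at 1232 ± 1008 and 190 ± 168 CPM. The unfolded protein response had a median of -0.20 (adjusted p = 0.0259, adjusted p = 0.459 with an estimated correlation) and cholesterol synthesis -0.26 (adjusted p = 0.0259, adjusted p = 0.68 with an estimated correlation). Lysosome genes were higher, with a median of 0.48 (adjusted p = 0.00582, adjusted p = 0.68 with an estimated correlation), 29 of 40 above 0 (medians of -0.20 in replicate numbers 1 and 2 and 1.06 in 3 and 4) and Cd63 at 564 ± 348 and 1851 ± 554 CPM. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.16 (adjusted p = 0.0389, adjusted p = 0.763 with an estimated correlation), with 36 of 43 above 0, and medians of -0.23 in replicate numbers 1 and 2 and 0.59 in 3 and 4 (interaction adjusted p = 4.3e-06 with camera, adjusted p = 0.429 with an estimated correlation). The direction turned and the call ended without CD replicates 3 and 4 for oxidative phosphorylation (median -0.10, adjusted p = 0.225 with camera) and for inflammasome and pyroptosis genes (median 0.08, adjusted p = 0.929 with camera). Cholesterol synthesis (median -0.59) and lysosome genes (0.28) were still called. The inflammasome median was -0.29 within replicate numbers 1 and 2 and -0.51 within 3 and 4. Adjusted over the list alone, 1 lysosome gene and 1 gene of the unfolded protein response, Trib3, were higher, and 0 passed in the inflammasome, cholesterol and oxidative phosphorylation lists (edgeR, 1 higher and 5 lower, 0 higher and 5 lower, and 2 higher and 0 lower at an unadjusted p under 0.05).

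Leaving out single libraries ended some of these calls (adjusted p with camera without the library named). For chemokines it was 0.0725 without CD replicate 1 and 0.101 without HFD replicate 1, and for conventional dendritic cells 0.0702 without CD replicate 2 and 0.0565 without HFD replicate 4. For erythroid cells and platelets it was 0.0725 without CD replicate 3 and 0.0689 without HFD replicate 1, and for lysosome 0.0629 and 0.190 without HFD replicates 3 and 4. For MHC class I presentation it was 0.115, 0.0671 and 0.411 without CD replicates 1 and 2 and HFD replicate 1. For cholesterol synthesis it was 0.283 and 0.256 without CD replicates 1 and 2 and 0.110 and 0.228 without HFD replicates 3 and 4. For the unfolded protein response it was 0.0930 and 0.0616 without CD replicates 1 and 2 and 0.0964 and 0.0771 without HFD replicates 3 and 4. For inflammasome and pyroptosis it was 0.0725 and 0.0897 without CD replicates 3 and 4 and 0.0567 and 0.0860 without HFD replicates 1 and 2. For oxidative phosphorylation, nuclear encoded, it was 0.223 and 0.442 without CD replicates 3 and 4 and 0.1202 and 0.444 without HFD replicates 2 and 4.

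Other settings ended these calls too. With camera they held in 23 of 28 alternative fits for chemokines and lysosome genes, 22 of 27 for conventional dendritic cells and for MC38 or other epithelial cells, and 15 of 20 for the joint list of eosinophils, mast cells and basophils. They held in 20 of 28 for erythroid cells and platelets, 19 of 28 for MHC class I presentation, the unfolded protein response and inflammasome genes, 17 of 27 for cholesterol synthesis and 12 of 28 for oxidative phosphorylation. With no filter on low counts the calls ended for all of these lists except lysosome and oxidative phosphorylation. With the hepatocyte covariate they ended for all except lysosome, cholesterol synthesis and conventional dendritic cells, and the lists of inflammasome and pyroptosis (median 0.72, adjusted p = 0.00628) and of erythroid cells and platelets (median 1.32, adjusted p = 0.00675) were called higher in HFD. That covariate itself separates the diets, so these changes cannot be told apart from an adjustment for diet. Another scaling or limma on FPKM ended the call for cholesterol synthesis (median 0.03 with limma on log2(FPKM + 1), 0.16 on the TPM scale and 0.13 with library size only, against -0.26), for MHC class I presentation and the unfolded protein response (library size only) and for oxidative phosphorylation (RLE factors, a median shift per library and limma on log2(FPKM + 1)). The lysosome call also ended with a mean FPKM of at least 5, within replicate numbers 1 and 2 and with the division plus the neutrophil covariate.

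No call was made for the remaining 23 lists with camera. Median log2 fold changes, with adjusted p in brackets, were 0.39 (0.0647) for hypoxia response, -0.27 (0.125) for alternative activation and immunosuppression, 0.54 (0.145) for lipid-associated macrophage genes, 0.13 (0.162) for phagocytic and efferocytic receptors and 0.20 (0.592) for complement. They were 0.07 (0.325) for fatty acid synthesis and desaturation, -0.77 (0.325) for MHC class II presentation, -0.19 (0.321) for matrix remodelling, 0.27 (0.325) for angiogenic factors and -0.26 (0.428) for NRF2, iron and oxidative stress. For further lists they were 0.08 (0.363) for prostaglandin and leukotriene synthesis, -0.18 (0.232) for mitochondrially encoded transcripts, 0.24 (0.676) for immediate early genes, -0.24 (0.889) for heat shock genes and -0.28 (0.666) for sex-linked transcripts. Among marker lists they were 0.20 (0.467) for sort markers and pan-macrophage genes, -0.27 (0.333) for non-classical monocytes, -0.33 (0.513) for plasmacytoid dendritic cells, -0.56 (0.592) for B and plasma cells, 0.46 (0.516) for fibroblasts and stellate cells and -0.41 (0.265) for endothelial cells. Median, mean and test differed in sign for lipid uptake, storage and efflux (median 0.17, mean -0.04, camera lower, adjusted p = 0.953) and for glycolysis (median 0.27, mean -0.03, camera higher, adjusted p = 0.706). Of these lists, 4 were called without CD replicates 3 and 4: MHC class II presentation (median -1.16, adjusted p = 1.6e-08), heat shock genes (-0.65, 2.2e-05), hypoxia response (0.50, 5.1e-04) and endothelial cells (-0.57, 0.00214).

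All 35 ways of dividing the 8 libraries into 4 and 4 were compared, the real one by diet included. For genes, 2 of 35 gave at least 1 call, the real one with 1 and 1 other with 1178, so chance cannot be excluded. That other one parts replicate numbers 1 and 2 from 3 and 4, which points to a structure of the samples other than diet. For lists, 2 of 35 gave at least 23 calls, the real one with 23 and 1 other with 26, so chance cannot be excluded there either. Divisions with 2 libraries of each diet on either side called from 1 to 21 lists. Camera calls at the preset correlation were therefore common without a diet contrast, and their adjusted p values alone do not show a diet difference. With the term for the replicate numbers, the real division gave 356 calls and the highest of the others 1, so that 1 of 18, the real one itself, reached its count. With the replicate block, 8 of 8 reached the real count of 0, and the highest of the others was 0. These divisions are too few for a share under 0.05.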
